A study of Homo sapiens with 14 samples.

How the data were processed

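RNA was measured in skin biopsies of people with dermatomyositis, an autoimmune disease of skin and muscle, taken before and 3 months after the start of apremilast, an oral inhibitor of the phosphodiesterase 4 enzymes that degrade cyclic AMP. Per the labels, biopsies were flash frozen, RNA was purified on columns and libraries were sequenced as paired reads of 100 bp. The deposited table holds estimated counts, 1 value per gene name and library, which need not be whole (54.2% to 67.5% of values per library, zeros included, were exactly whole). Kallisto 0.46.0, STAR 2.6.1d and the hg38 genome are named in the submitters' processing notes, without their order or settings. The annotation and the use of strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated, and genes with near-identical copies (C4A and C4B, FCGR3A and FCGR3B, the KRT6 genes, HBA1 and HBA2) are uncertain.

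The table has 57152 rows and 14 columns, 7 before and 7 after treatment, with a patient number in each name. Of the gene names, 56963 were found in GENCODE release 29, the source of the GRCh38 coordinates given here, and 27 rows held a date in place of a gene name. The 514 rows of Y-linked genes, XIST and TSIX were left out. After columns of 2 patients held identical values in every row. They are 1 library under 2 labels, and the labels do not tell to which patient it belongs, so it was counted once. This left 13 distinct libraries, 7 before and 6 after, and 5 intact pairs.

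The planned design was a fit with the patient as a block, since the labels take both biopsies from each patient. It was kept, on the 10 libraries of the 5 intact pairs, with 4 residual degrees of freedom. Same-patient biopsies deviated together: the correlation of their deviations from the group means was between 0.290 and 0.545 in 5 of 5 pairs, against a median of -0.0662 between different patients, and the own partner correlated best in 5 of 5. This was settled before calls were compared. All 13 libraries entered a fit without the block.

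Estimated counts were rounded. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Per-group levels are CPM, the counts scaled to a common library size, as mean ± SD. The 34 gene lists (701 distinct genes) were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 (and with estimated correlations) and with fry, adjusted over the lists. List scores are the mean log2 CPM (prior count 2) of the tested members. After minus before was tested by an exact two-sided sign-flip test over the 5 pairs, where the smallest p is 0.0625. All 13 libraries were tested by an exact two-sided permutation of the labels (1716 arrangements), which ignores the pairing.

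The genes to be named were also fixed in advance: 33 genes, the 4 members with the smallest p of each list described, and, as fewer than 5 genes passed in each direction, the 10 with the smallest p per direction at a mean log2 CPM of at least 1. The rule asked for 6 of 7 pairs in one direction, which became 4 of 5 here. Of the genes so picked, 2 are not reported here. A planned correlation of list changes across patients was not run, because 5 intact pairs are below the minimum of 6.

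On simulated counts for the comparison of after with before in the 5 pairs (23755 genes), the fit recovered 58 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 14 false calls. Camera and fry both called the 1 shifted list and 0 of 33 unshifted lists. The simulation drew genes independently, so it does not carry the correlation between genes of a list. The changed genes were picked at random and had the same change in every patient. The recovered shares therefore do not hold for genes whose change differs between patients. In the type I interferon list the median SD of the pair differences was 1.83, against 0.31 for random lists matched on expression.

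Total counts ran from 10815577 to 49065178 per library. Alternatives were other scalings (RLE, upper quartile), filters, robust fitting, DESeq2 1.42.0 with the block, limma 3.58.1 voom with the patient as a random effect on 13 libraries, no block, and each pair left out. Chosen after seeing the data were the fits with the repeated library given to either patient, the 14 columns as deposited, other subsets without the block, and mitochondrial transcripts left out or their share as a covariate. Patients are separate people, so the spread between pairs is biological as well as technical. There was no untreated group.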

Results

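Skin RNA was profiled in 7 patients with dermatomyositis before and after 3 months of apremilast. The deposited values form 13 distinct libraries, 7 before and 6 after treatment, since 2 of the 14 columns hold 1 library. Total counts averaged 37675900 ± 14143100 (SD, n = 7) before and 35528000 ± 6768880 (SD, n = 6) after. The shallowest library, taken before treatment, had 10815577 counts and the next 26381266. Mitochondrial transcripts took 15.8% ± 6.96 (SD, n = 7) of the counts before and 19.1% ± 4.36 (SD, n = 6) after, and their share was higher after treatment in 4 of 5 intact pairs (exact sign-flip p = 0.188). Patients accounted for a median of 59.5% of the variance of a gene over the 5 pairs and treatment for 7.14%. Chance alone gives mean shares of 44.4% and 11.1%. A median can lie below such a mean, so 7.14% does not show that treatment accounted for less than chance.

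The first question was which transcripts differ in skin after treatment. Over the 5 pairs, interferon-induced chemokines had the largest differences among the genes fixed in advance. CXCL9, CXCL10 and CXCL11, ligands of CXCR3, a chemokine receptor of T cells, had log2 fold changes of -4.05 ± 0.96, -4.94 ± 1.39 and -5.57 ± 1.60 (SE, 5 pairs). On 13 libraries and with no patient block they were at -3.58, -2.50 and -2.73, and IFNG (-2.80) lay beyond CXCL10 and CXCL11. CXCL10 and CXCL11 were lower in 4 of 5 pairs and higher in 1. CXCL9 was lower in 5 of 5 pairs, and averaged 227 ± 216 CPM before (SD, n = 7) and 18.9 ± 23.9 CPM after (SD, n = 6). The antiviral effectors ISG15 (-3.46 ± 0.95) and MX1 (-2.35 ± 0.80) and the interferon signal transducer STAT2 (-1.21 ± 0.43) were each lower in 4 of 5 pairs and higher in 1, while STAT3 stood at -0.17 ± 0.14. On 13 libraries with no patient block ISG15, MX1, STAT2 and STAT3 were at -1.91, -1.76, -1.26 and -0.13. None of these differences passed the threshold over all genes in edgeR, with adjusted p of 0.343 for CXCL9 and 0.351 for MX1. DESeq2 called CXCL9, CXCL10, CXCL11, ISG15 and STAT2 but not MX1 (adjusted p = 0.123) or STAT3.

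Over all genes, edgeR tested 23755 and called 0 lower and 0 higher after treatment. The smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 1796 lower and 1109 higher genes, where 1188 in all are expected by chance. With 1 pair left out these counts were as low as 862 and 532. With upper-quartile scaling that split was 1519 lower and 1542 higher. Without the patient block, on 7 before and 6 after libraries, edgeR again called 0 and 0, with 1408 lower and 594 higher at an unadjusted p under 0.05. The tools differed: DESeq2, with the block, called 636 lower and 117 higher, among them 19 of 40 type I interferon, 27 of 34 interferon-gamma and 17 of 23 macrophage genes lower, and limma voom called 0 and 0 (2252 and 1621 at an unadjusted p under 0.05).

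The 10 genes with the smallest p among those lower after treatment, all with an edgeR adjusted p of 0.343 and so short of the threshold, were lower in 5 of 5 pairs. The first was THY1, a surface glycoprotein of fibroblasts and endothelium (chromosome 11, 119417378 to 119424985, minus strand), at -1.21 ± 0.18, from 124 ± 56.8 CPM before to 61.4 ± 20.5 after. It was followed by SRPX (chromosome X, 38149336 to 38220924) at -0.87 ± 0.13 and CHN1 (chromosome 2, 174799363 to 175005369) at -1.12 ± 0.17. DUSP1, a phosphatase of MAP kinases, stood at -1.03 ± 0.17 and TCIM at -1.14 ± 0.19. Also among them were FAM20A, TNFRSF12A (the receptor of the cytokine TWEAK), VAMP5 and the prostaglandin transporter SLCO2A1, between -1.09 and -0.74. DESeq2 called each gene named in this paragraph, from an adjusted p of 6.1e-06 for THY1 to 0.00088 for SLCO2A1. The genes were picked by their p on the same pairs, so these calls are not separate support.

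Among genes higher after treatment, the 10 with the smallest p were likewise higher in 5 of 5 pairs with an adjusted p of 0.343. They were ABCA5, a lipid transporter (0.67 ± 0.12, chromosome 17, 69244311 to 69327244), the zinc finger genes ZNF711 (0.73 ± 0.13) and ZNF273 (0.71 ± 0.14), EMILIN3 (1.01 ± 0.18), ZC2HC1A (0.64 ± 0.11), FCGBP (0.78 ± 0.14), the potassium channel KCNA2 (0.92 ± 0.17), TNFRSF19 (0.69 ± 0.13), UGT2A1 (1.21 ± 0.24) and the prolactin receptor PRLR (0.75 ± 0.15). FCGBP averaged 32.8 ± 17.8 CPM before (SD, n = 7) and 67.8 ± 27.0 after (SD, n = 6). DESeq2, on the same pairs, called each of these genes, from an adjusted p of 0.00088 for EMILIN3 to 0.0060 for ZNF273.

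**Figure D1:**
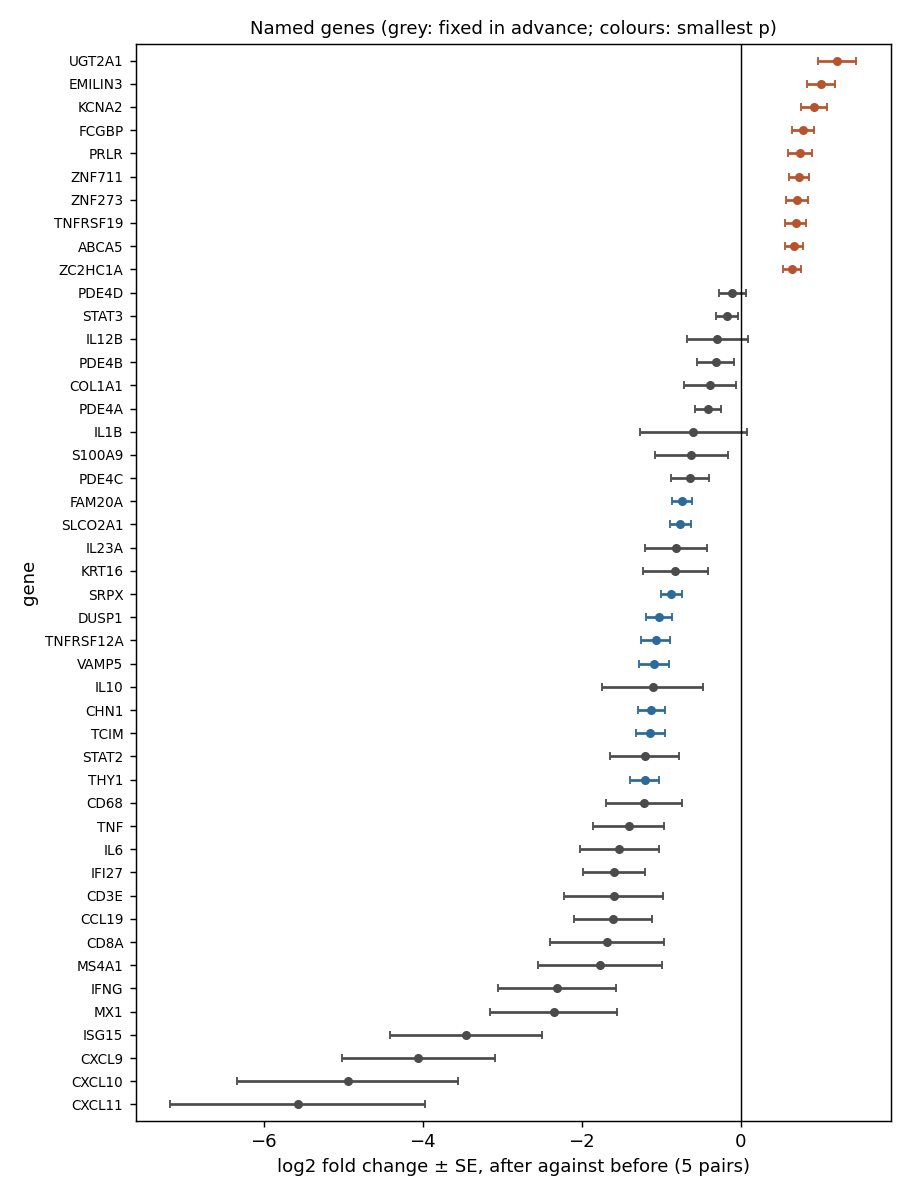
Log2 fold change with its SE (horizontal axis) of each named gene (vertical axis), after against before treatment, over 5 pairs with the patient as a block. Grey points are genes fixed in advance and coloured points those with the smallest p in each direction. CXCL11 lies farthest to the left at -5.57 ± 1.60, and no gene passed the edgeR threshold over all genes.

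The transcripts of the drug's targets were measured, not the enzymes or their activity. Before treatment PDE4A, PDE4B and PDE4D averaged 25.4 ± 4.42, 19.7 ± 4.38 and 19.1 ± 4.73 CPM (SD, n = 7), and PDE4C 1.29 ± 0.384 CPM. CPM is not scaled for gene length, so levels of different genes are not compared here. Their log2 fold changes were -0.41 ± 0.16, -0.31 ± 0.24, -0.10 ± 0.18 and -0.64 ± 0.24, and 0 of 4 passed when adjusted over the list alone. Of the cytokines fixed in advance, TNF stood at -1.41 ± 0.44 and IL6 at -1.53 ± 0.50, IFNG at -2.31 ± 0.75, IL10 at -1.11 ± 0.63, IL1B at -0.60 ± 0.67, IL23A at -0.81 ± 0.40 and IL12B at -0.29 ± 0.38, none past the edgeR threshold, while DESeq2 called TNF (adjusted p = 0.0181). With the mitochondrial share as a covariate IFNG was at -0.058 and PDE4B at -0.0058, and PDE4D (0.056), IL10 (0.25), IL1B (0.51) and IL12B (0.30) changed sign. IFNG, IL6, IL23A and IL12B averaged 0.72, 0.75, 1.21 and 1.25 CPM before (n = 7) and 0.10, 0.30, 0.69 and 0.97 after (n = 6). Their fold changes thus rest on low counts. IFNG passed the filter in 14 alternative settings, against 21 for TNF. IL17A had 0 reads in 13 libraries. IFNB1, IL4, IL13 and IL31 had too few counts for a test, with at most 20 in any library.

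The second question was whether gene groups moved together. Interferon-induced genes were lower on average. All 40 tested members of the type I interferon list were lower, with a median log2 fold change of -1.94, and 38 of 40 passed when adjusted over the list alone against 0 over all genes in edgeR. Without the patient block, on 13 libraries, 0 of 40 passed over the list alone (median -1.49). IFI27 (-1.59 ± 0.40), IFITM3 (-1.32 ± 0.33), BST2, which tethers virions to the cell (-2.16 ± 0.56), and IFI6 (-2.71 ± 0.71) had the smallest p. Of the interferon-gamma list, 34 of 34 members passed when adjusted over the list alone, with a median of -1.48, and 30 of 34 without the block. They included the immunoproteasome subunits PSMB9 (-1.51 ± 0.36) and PSMB10 (-1.28 ± 0.33), and HLA-DMB (-0.98 ± 0.24), which loads peptides on class II molecules. The camera adjusted p of both lists was 2.1e-38 with the preset correlation, and adjusted p = 0.33 with an estimated correlation, so neither call holds there. With the mitochondrial share of each library as a covariate, a fit added after seeing the data, the medians were -0.88 and -0.74. That share went with the type I interferon score also among libraries before treatment, so the covariate may take out part of the difference itself.

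Macrophage and lymphocyte markers were lower on average as well, while the mast cell list was at 0.05 with 9 of 13 members higher. In the macrophage and monocyte list 21 of 23 members were lower and past the threshold when adjusted over the list alone (median -1.36), led by the signalling adaptors TYROBP (-1.48 ± 0.32) and FCER1G (-1.52 ± 0.38), AIF1 (-1.26 ± 0.30) and the Fc receptor FCGR3A (-2.50 ± 0.66). The T cell list had a median of -1.49, all 22 members below 0 and 3 of 22 past the threshold over the list alone, with CTLA4 (-1.98 ± 0.48), CD4 (-1.10 ± 0.28), ICOS (-2.12 ± 0.55) and CD27 (-1.56 ± 0.46) first. Cytotoxic lymphocyte genes had a median of -1.65 and 9 of 22 past it, among them CCL4 (-2.30 ± 0.61), granzyme B (GZMB, -3.33 ± 0.91), granulysin (GNLY, -2.39 ± 0.70) and CCL5 (-2.26 ± 0.72). In the dendritic and Langerhans cell list 10 of 19 passed (median -0.73). They included the plasmacytoid dendritic cell markers LILRA4 (-3.36 ± 0.67) and CLEC4C (-2.27 ± 0.61), CLEC9A (-1.23 ± 0.33) and CCR7 (-2.26 ± 0.66). In that list 5 members lay above 0, among them the Langerhans cell markers CD207 (0.53 ± 0.29) and CD1A (0.67 ± 0.38), which are named after their values were seen and did not pass. Camera called all 4 lists lower with the preset correlation, and none with an estimated one (adjusted p = 0.33 for each). Without the patient block 7 of 23 macrophage, 17 of 22 T cell, 20 of 22 cytotoxic and 3 of 19 dendritic genes passed over the list alone. With the mitochondrial share as a covariate the macrophage, T cell, cytotoxic and dendritic medians were -0.62, -0.70, -0.41 and -0.55. CD3E, CD8A, MS4A1 and CD68 stood at -1.59 ± 0.62, -1.68 ± 0.72, -1.77 ± 0.77 and -1.22 ± 0.48, and with that covariate at -0.67, -0.18, 0.32 and -0.38.

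Inflammatory mediators showed the same direction. The TNF and NF-kB list had 17 of 27 members lower and past the threshold when adjusted over the list alone (median -0.96), with the endothelial adhesion molecule SELE (-2.57 ± 0.54), PTGS2, the inducible cyclooxygenase (-1.29 ± 0.33), BCL3 (-0.76 ± 0.19) and RELB (-1.03 ± 0.27) first. Of the complement list 17 of 18 were lower (median -0.94) and 11 of 18 passed over the list alone, against 0 of 18 without the patient block, with C4B (-1.17 ± 0.21), whose reads cannot be told from C4A, C5AR1 (-1.25 ± 0.30), C2 (-1.28 ± 0.33) and CFB (-1.94 ± 0.52). JAK-STAT components had a median of -0.41 and neutrophil markers of -1.02, with 0 of 28 and 0 of 13 past the threshold over the list alone. With an estimated correlation camera gave an adjusted p = 0.33 for each of these 4 lists as well. Over the list alone 14 of 27 TNF, 5 of 28 JAK-STAT and 5 of 13 neutrophil genes passed without the patient block. With the mitochondrial share as a covariate the TNF, complement, JAK-STAT and neutrophil medians were -0.46, -0.57, -0.24 and -0.18, and camera no longer called the neutrophil list with the preset correlation (adjusted p = 0.317). The CCR7 ligand CCL19 stood at -1.61 ± 0.50, the stress keratin KRT16 at -0.82 ± 0.41 and the neutrophil and keratinocyte protein S100A9 at -0.62 ± 0.46.

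Fat, gland and pigment cell markers lay in the other direction. All 16 adipocyte genes were higher (median 0.71), 9 of 16 past the threshold over the list alone, with PLIN1, which coats lipid droplets (0.83 ± 0.23), FABP4 (0.63 ± 0.19), adiponectin (ADIPOQ, 0.76 ± 0.23) and TRARG1 (0.80 ± 0.25). Melanocyte genes had a median of 0.71 and 3 of 12 past it, among the enzymes and channels of pigment cells DCT (0.99 ± 0.23), TRPM1 (0.84 ± 0.22), SLC24A5 (0.79 ± 0.23) and TYRP1 (0.70 ± 0.24). The sebaceous gland list had the highest median, 1.01, with 0 of 15 past it, as in ACSBG1 (1.14 ± 0.32), FADS2 (1.29 ± 0.45), FAR2 (0.90 ± 0.34) and MC5R (0.76 ± 0.29). With an estimated correlation camera gave these lists an adjusted p = 0.33. With no patient block 0 adipocyte and 0 melanocyte genes passed over the list alone, and the adipocyte, melanocyte and sebaceous medians were 0.38, 0.83 and 0.43. With the mitochondrial share as a covariate they were 0.67, 0.26 and 1.34. Fibroblast and matrix genes had a median of -0.28 (camera adjusted p = 2.5e-05 with the preset correlation, and adjusted p = 0.47 with an estimated correlation or 0.186 without the patient block), with THY1 and lumican (LUM, -0.69 ± 0.17) the 2 of 23 past the threshold over the list alone. COL5A2 (-0.51 ± 0.17), FN1 (-0.44 ± 0.17) and COL1A1 (-0.39 ± 0.33) did not pass. The endothelium list was at -0.12.

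**Figure D2:**
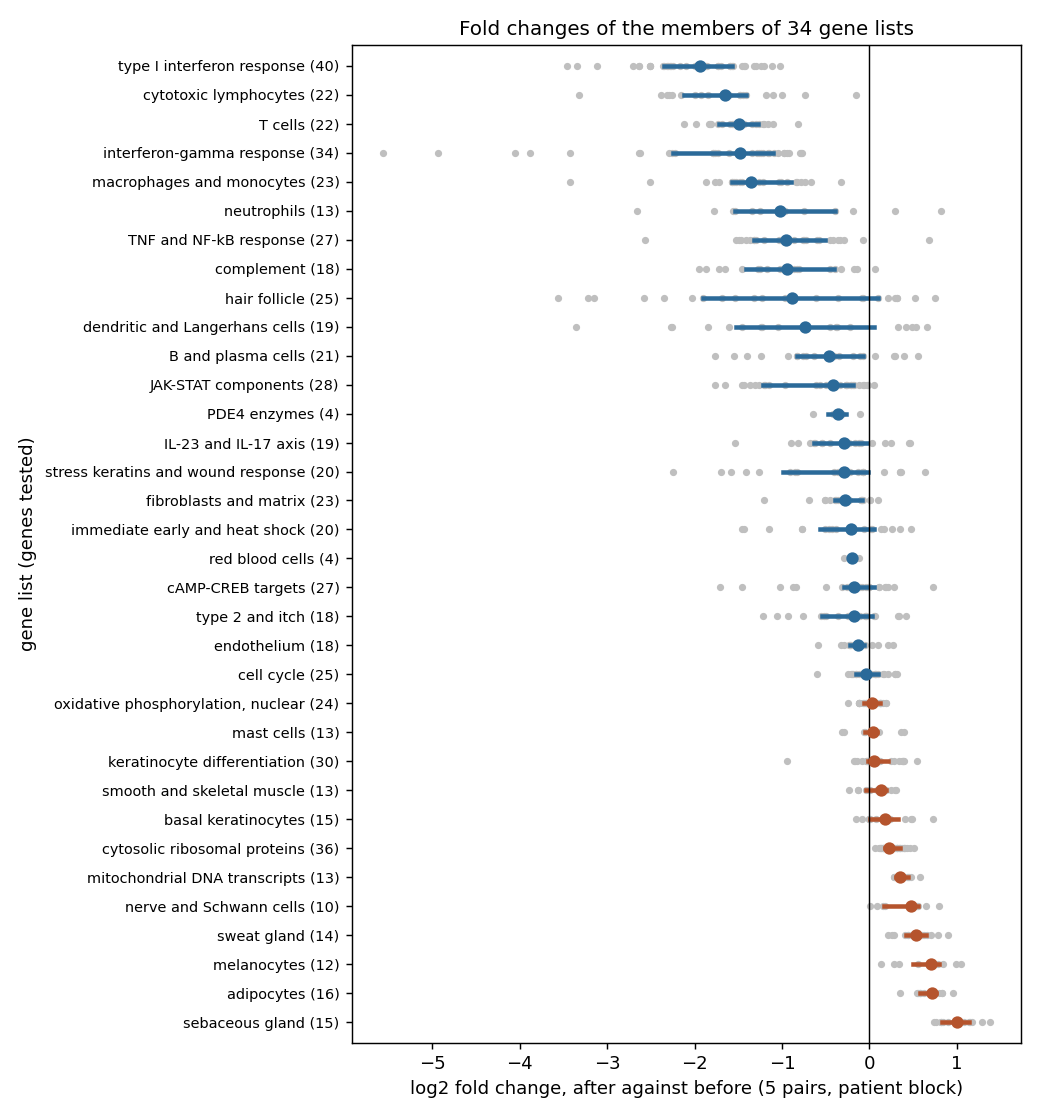
Log2 fold changes after against before treatment (horizontal axis) of the tested members of 34 gene lists (vertical axis, number tested in brackets). Small grey points are genes, large points the list median and bars the span between the quartiles of the members, blue for a negative and orange for a positive median. Medians run from -1.94 for type I interferon to 1.01 for the sebaceous gland.

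In all, camera with the preset correlation called 18 of 34 lists lower and 8 higher, and with estimated correlations (median 0.611) it called 0, with adjusted p from 0.328 to 0.955. In other groupings of the same libraries the preset correlation also called many lists, a median of 19 over the 15 other within-pair arrangements, so its calls are descriptions here. In the test for change in one direction fry called 0 lists, its smallest adjusted p being 0.248.

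The third question was how many patients moved each way. The type I interferon score was 7.06 ± 1.85 log2 CPM before (SD, n = 7) and 5.21 ± 1.56 after (SD, n = 6). It was lower after treatment in 4 of 5 pairs, by a mean difference of -1.94 ± 1.75 (SD, 5 pairs), and single differences ran from -3.68 to 0.25. The exact sign-flip p was 0.125 and the adjusted p 0.354. With the repeated library given to the first or second patient, over 6 pairs, the mean difference was -1.60 ± 1.77 or -2.34 ± 1.85 (SD). The sign-flip p were then 0.125 and 0.0625. The interferon-gamma score differed by -1.80 ± 1.42 and was lower in 4 of 5 pairs, and the macrophage score by -1.33 ± 1.10 and lower in 5 of 5. The T cell and cytotoxic scores differed by -1.50 ± 1.50 and -1.56 ± 1.54, each lower in 4 of 5. The same pair was the exception for the type I interferon, interferon-gamma, T cell and cytotoxic scores. Its type I interferon score was 8.05 before and 8.31 after. With that pair left out, the mean type I interferon difference was -2.48 ± 1.44 (SD, 4 pairs). The sign-flip p was then 0.125, the smallest possible with 4 pairs. TNF and complement scores were lower in 5 of 5 pairs (-0.85 ± 0.73 and -0.95 ± 0.69), and the adipocyte score was higher in 5 of 5 (0.69 ± 0.67). The spread of the pair differences was about as large as their mean for most of these lists. With 5 pairs the exact sign-flip test cannot go below p = 0.0625, so 0 of 34 lists could pass. The permutation of the 13 libraries ignores the pairing, so differences between patients enter it. Over all 13 libraries the exact permutation p was under 0.05 for 5 of 34 lists, 0.0239 for neutrophil, 0.0344 for interferon-gamma, 0.0355 for JAK-STAT, 0.0408 for TNF and NF-kB and 0.0466 for cytotoxic genes, and 0 of 34 passed after adjustment (each adjusted p = 0.286).

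**Figure D3:**
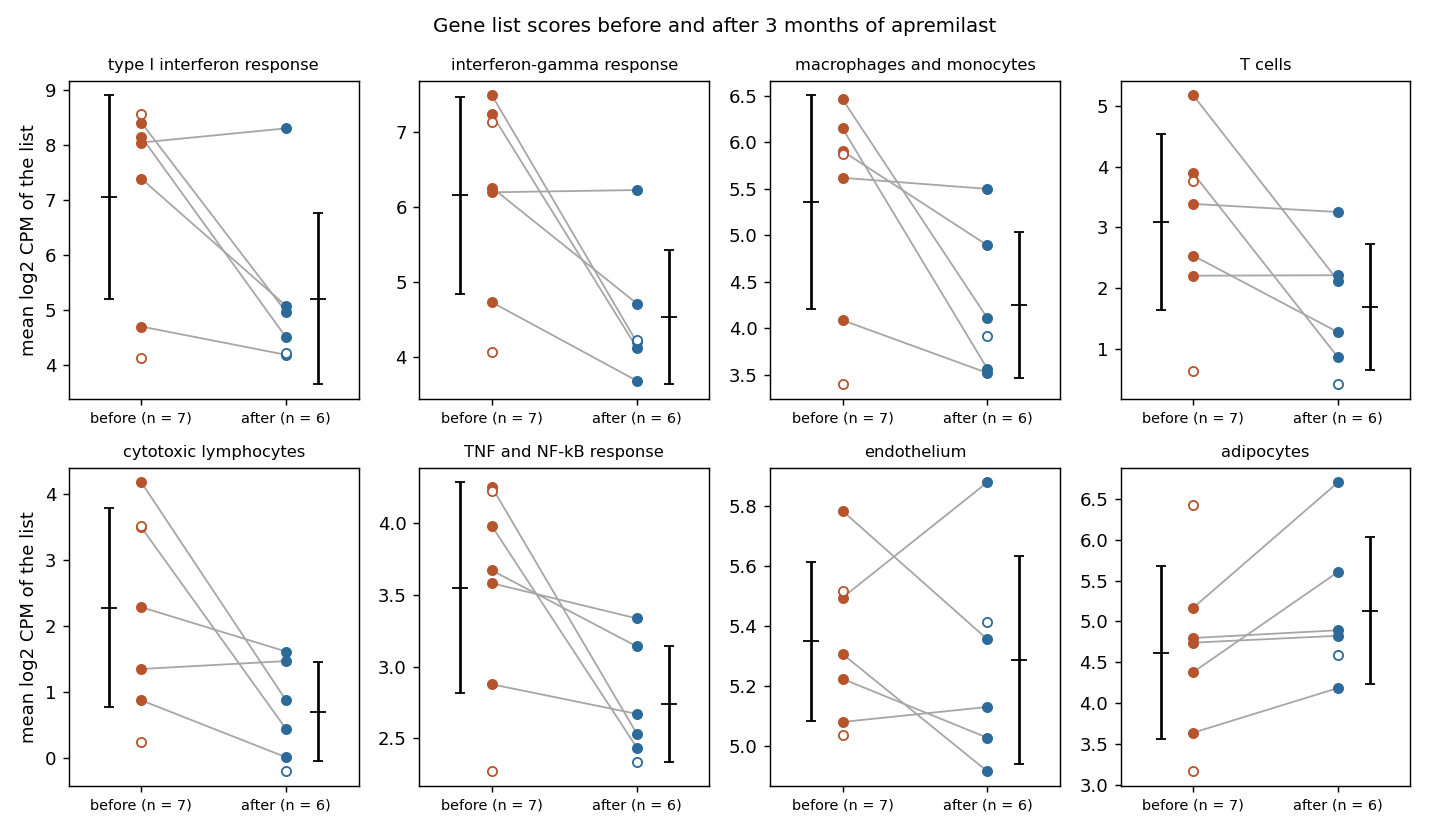
Scores of 8 gene lists (vertical axis, mean log2 CPM of the members) in each library before (orange, n = 7) and after treatment (blue, n = 6). Grey lines join the 5 intact pairs, open circles are libraries in no pair, and black bars show mean ± SD. The type I interferon score is lower after treatment in 4 of 5 pairs, and endothelium differs little (mean difference -0.12 ± 0.34, SD).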

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

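Tests of explanations other than the counts over other groupings of the libraries were chosen after the result they bear on was seen. In 114 sets of values, a library or pair stood far from the others in 9, where chance flags about 1 in 20, or 5.7. The sets overlap in their libraries, and 4 of the 9 values belong to the shallowest library: the low PDE4 and neutrophil scores, the high ribosomal protein score and the low number of genes.

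After treatment, 1 of 6 libraries had a type I interferon score of 8.31 log2 CPM and the next highest 5.08 (gap over range 0.784). It is the after library of an intact pair, whose before score was 8.05. Before treatment, 1 of 7 libraries had a red blood cell score of 6.89 and the next 3.07 (0.804). In sets of 7 before libraries, the PDE4 score had a low value of 2.84 (0.612), the mast cell score a high value of 4.36 (0.590), the neutrophil score a low value of -0.04 (0.712), the fibroblast score a high value of 8.75 (0.604) and the ribosomal protein score a high value of 9.81 (0.583). The shallowest library had 17198 genes with at least 10 counts and the next 22774 (0.660). Among the 5 pair differences, the B and plasma cell score had a low value of -1.92 with the next at -0.29 (0.716).

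The interferon, macrophage, lymphocyte and inflammatory lists were lower after treatment. The shallowest library does not account for it, since without its pair the type I interferon median was -2.35. Less dermis in the later biopsies was weighed for macrophages alone, by their change minus the endothelium change. The mean was -1.21 ± 0.56 (SE, 5 pairs), a margin too small over so few pairs to decide. Whether the mitochondrial share accounts for the lower lists is not settled. With it as a covariate the median was -0.88, with a median SE of 0.36 and 40 of 40 members below 0. Too few degrees of freedom remain to decide. The share also went with the type I interferon score within the groups. Before treatment the library with the highest share (26.1%) had the lowest score (4.13), and that with the lowest (9.02%) the highest (8.57). After treatment the library with the lowest share (11.8%) had the highest score (8.31), and that with the highest (24.4%) scored 4.97. The covariate may thus take out part of the interferon difference itself. The course of the disease without the drug and chance remain open too, as there was no untreated group.

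Adipocyte and melanocyte lists were higher after treatment. A lower share of leukocytes would raise endothelium alike, if endothelial transcripts did not change otherwise. The adipocyte change exceeded the endothelium change by 0.81 ± 0.25 (SE, 5 pairs). This cannot decide, since the pairs are few and endothelial genes can change themselves, as in SELE (-2.57 ± 0.54). Deeper biopsies could account for adipocytes, where the difference from basal keratinocytes, 0.50 ± 0.38 (SE), cannot decide. They would not raise melanocytes, cells of the epidermis, whose score was higher by 0.64 ± 0.27 (SE). The melanocyte score was higher in 4 of 5 pairs (exact sign-flip p = 0.125), which cannot decide either. Treatment itself was not separated from time.

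Median fold changes of several lists were far from 0 while edgeR called no gene, and over the 5 pairs no test that allows for the correlation between genes called those lists in one direction. Patients differing in the size of their change is a candidate explanation: the median SD of the pair differences over the type I interferon genes was 1.83, above all 10000 random lists matched on expression (percentile 100, their median 0.31). That comparison cannot decide, since a large fold change short of the threshold already implies a large spread. The random lists also held genes drawn separately, while members of this list moved nearly together (estimated correlation 0.963). Pairs lost to the repeated library remain open as an explanation. Giving that library to either patient, over 6 pairs, called 0 genes at the threshold. The smallest edgeR adjusted p was then 0.414 with the first patient and 0.174 with the second, against 0.343 over the 5 pairs. These fits cannot decide, since the labels do not tell which assignment is right and neither restores every planned pair.

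Chance was weighed by regrouping the libraries. The 5 pairs allow 16 arrangements, too few for a share under 0.05. The real one had 2905 genes at an unadjusted p under 0.05 and the highest other 3011 (2 of 16 as large), camera called 26 lists and at most 26 in another (2 of 16), and edgeR genes at the adjusted threshold and fry lists in one direction numbered 0 in 16 of 16, which decides nothing. The 100 splits drawn from the 1716 into 7 and 6 libraries ignore the pairing, so differences between patients enter them, and they test only the fit without the block. For that fit chance could not be excluded: 21 splits gave at least the real 2002 genes (highest other 5339) and 34 at least the real 22 camera lists (highest 27). With 0 adjusted genes and 0 fry lists in the real split, all 100 splits have as many, which decides nothing (highest other 603 and 14). The 6 other splits with any adjusted gene may follow a structure of the samples other than treatment, and which one was not tested.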

How the results depend on the processing

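The 0 calls of edgeR held under RLE and upper-quartile scaling, the stricter filter, robust fitting, a threshold of 0.10, each pair left out (0 to 0 in each direction) and no patient block (0 lower, 0 higher). DESeq2 called 636 lower and 117 higher genes, the unfiltered fit 10 and 1, and the added fit with the mitochondrial share as a covariate 1 and 0 (CXCR5, named after its value was seen, adjusted p = 0.0392 against 0.343). The cause was not tested. Unadjusted counts ran from 862 to 1995 lower and 532 to 1579 higher with 1 pair left out. Without the block they were 1408 and 594, and also without the repeated library 1097 and 384. Camera called 15 to 18 lists lower and 6 to 9 higher with 1 pair left out, 0 and 0 with estimated correlations, and 3 higher with the mitochondrial covariate. Fry, testing for change in one direction, called 0 to 0 with 1 pair left out and 1 (neutrophils, adjusted p = 0.0336) without the block and the shallowest library, a subset chosen after seeing the data. Sign-flip scores called 0 lists in each setting run, an outcome that 5 or fewer pairs fix. With 6 pairs the smallest sign-flip p is 0.03125, so a list could pass after adjustment only if most lists reached it. The smallest adjusted p there were 0.327 and 0.212, which says little. The outcome was not fixed in the permutation of 13 libraries, which ignores the pairing and also called 0. Without the block camera called 15 lists lower and 7 higher with the preset correlation. It lost fibroblasts (adjusted p = 0.186), type 2 and itch (0.128), the cAMP and CREB list (0.0703) and sweat gland (0.0703). The type I interferon median ran from -2.51 to -0.88, below 0 in 19 of 19 settings.

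Changes of sign, cause not tested: without the block the hair follicle median was 0.31, with the stricter filter 0.17, with the repeated library given to the second patient 0.13, with 14 columns 0.43, without block and shallowest library 0.37. That last setting gave immediate early genes 0.00090. On the 5 pairs without block, mast cells were at -0.043, keratinocyte differentiation at -0.052 and nuclear oxidative phosphorylation at -0.015. Without block and repeated library, keratinocyte differentiation was at -0.027, sweat gland at -0.13 and muscle at -0.075. Red blood cells were at 0.10 with the second patient, and cell cycle at 0.011 with upper-quartile scaling. With the mitochondrial covariate, keratinocyte differentiation was at -0.14, sweat gland -0.085, nerve -0.0094, cell cycle 0.020, mitochondrial transcripts -0.11, oxidative phosphorylation -0.14, ribosomal proteins -0.15, PDE4D 0.056, IL10 0.25, IL1B 0.51, IL12B 0.30 and MS4A1 0.32. With 1 pair left out, medians ran from -0.16 to 0.014 for the cAMP and CREB list and -0.75 to 0.039 for B cells. They ran from -0.15 to 0.17 for mast cells, -0.15 to 0.18 for keratinocyte differentiation and -2.07 to 0.027 for hair follicle. Muscle ran from -0.0050 to 0.29, red blood cells from -0.39 to 0.019 and cell cycle from -0.054 to 0.056. Oxidative phosphorylation ran from -0.067 to 0.15. Fold changes ran from -0.18 to 0.078 for PDE4D and -1.07 to 0.018 for IL1B.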

Other observations

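The lists for cyclic AMP and for early stress had small negative medians. The cAMP and CREB list holds parts of the pathway, such as CREB1, CRTC1 and PRKACA, besides target genes. It is therefore not a measure of target genes alone. Of its 27 genes 20 were lower (median -0.18), 1 past the threshold over the list alone. DUSP1 (-1.03 ± 0.17), the nuclear receptor NR4A3 (-1.71 ± 0.46), CREM (-0.49 ± 0.14) and RGS16 (-0.84 ± 0.25) came first. Of 20 immediate early and heat shock genes 13 were lower (median -0.21) and 2 passed, among ZFP36, which destabilises cytokine mRNAs (-0.77 ± 0.17), ATF3 (-1.14 ± 0.30), FOS (-1.43 ± 0.42) and KLF6 (-0.50 ± 0.15). Fry, testing for change in either direction, gave these 2 lists adjusted p of 0.0053 and 0.023, the only 2 of 34 it called in that test. Without the patient block both calls were lost (adjusted p = 0.441 and 0.316), and DUSP1 was at -0.61. With the mitochondrial share as a covariate the medians were -0.0058, with 14 of 27 lower, and -0.19. Its directional adjusted p was 0.271 and 0.248, and camera with an estimated correlation gave adjusted p = 0.40 and 0.33.

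The medians of the other lists ran from -0.88 to 0.54. With the preset correlation camera called lower the B and plasma cell (-0.46), IL-23 and IL-17 (-0.29), type 2 and itch (-0.17), PDE4 (-0.36) and stress keratin lists (-0.29), and higher the sweat gland (0.54), nerve (0.48), mitochondrial DNA (0.35), cytosolic ribosomal protein (0.23) and basal keratinocyte lists (0.18). None was called with an estimated correlation (adjusted p from 0.328 over all lists). It did not call keratinocyte differentiation (0.06), hair follicle (-0.88, but -2.44 and called lower with the mitochondrial covariate and the preset correlation, adjusted p = 1.1e-08), mast cells (0.05), muscle (0.13), red blood cells (-0.20), cell cycle (-0.03) or nuclear oxidative phosphorylation (0.03).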
